A study of Mus musculus with 6 samples.

How the data were processed

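The data are 6 peak lists of ATAC-seq libraries from mouse Th17 cells, 3 ChAT-GFP-positive and 3 ChAT-GFP-negative. Per the labels' protocols, naive CD4+ T cells were isolated from spleen with an isolation kit and cultured with IL-1β at 20 ng/ml, IL-6 at 25 ng/ml and IL-23 at 20 ng/ml, with anti-CD3 and anti-CD28 at 2 µg/ml each. Tagmentation used a Nextera kit, per the labels' protocols. The submitters' processing notes name DiffBind 2.12.0 without its role. The aligner, the peak caller, the filters, any shift of reads for the transposase and the genome build are not given in the sources used here, so their effect on the lists could not be examined.

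The deposited lists have 1 line per summit and were made per library. The signal value per summit is the deposited output of the peak caller, and what it is relative to is not stated. The lists also give deposited −log10 p-values and q-values per summit and a deposited score, which equals 10 times the −log10 p up to a ceiling. These are the authors' own values per peak and were used only to rank or filter peaks within a list. No list gives read counts, so depth is unknown and no interval on a count of reads was computed. All lists reached down to a −log10 p of about 2, and the share of peaks with −log10 q of at least 3 was 80.1% in ChAT-GFP-negative replicate 2 and 92.2% to 96.0% in the others.

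Summits of 1 peak were collapsed to distinct peaks, and 1 absolute summit position in each of 2 lists was converted to an offset. Peaks of all lists were merged where they overlapped by at least 1 bp, and a list held a region where any of its peaks overlapped it. Positive-only regions were in all 3 positive and no negative list, and negative-only regions the reverse. Lists of equal length kept the 77644 peaks with the highest −log10 p. Counts were set beside the 10 splits of 6 lists into 3 against 3. Group means were compared by 2-sided exact permutation tests, whose smallest p is 0.1, and by sign flips over the 3 same-numbered pairs, whose smallest p is 0.25. Similarity was the Jaccard index of covered bases.

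The build was inferred from the lists. A summit lay within 500 bp of 26.8% to 31.5% of gene ends of the GRCm38.p6 gene table, and of 5.04% to 8.98% once the ends were shifted. Coordinates are those of the lists, counted from 1. The gene table gives spans without strand, exons or introns, so a region was assigned to the nearest protein-coding gene span within 50 kb in place of the planned nearest start site, and the planned promoter share became the share of regions within 1 kb of either gene end. A region inside a span could therefore not be placed in an exon, intron or UTR. The table held 21900 protein-coding genes, 17096 had a region, and all 336 genes of the fixed lists matched. Motif searches with 24 consensus sequences were planned and not run, since a genome sequence was not used here.

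The gene lists, culture descriptions and tests were fixed before the data were examined. The 23 lists covered cholinergic, Th17 core, pathogenic and non-pathogenic Th17, Th1, Th2, regulatory, follicular helper, naive and memory, activation, inhibitory receptor, AP-1 and BATF, NF-kB, chemokine receptor and homing, cell cycle, glycolysis, histone deacetylase, adrenergic and neuropeptide receptor and T cell lineage genes, and markers of B cells, CD8 T and NK cells, myeloid and dendritic cells and erythroid cells. Each list was compared with 10000 random lists matched on regions per gene, with Benjamini-Hochberg adjustment over 46 tests. Named genes were all cholinergic genes with a region, the 10 regions per direction with the highest value of their lowest within-list signal percentile, preferring those also found in lists of equal length, up to 4 members per list and direction, and a fixed set of reference loci, of which 1 is not reported here. Counts of gene ends with a peak, regions per 1000 of a list, gene lists per culture, the strongest regions per culture and the rank of Chat were added after seeing the data.

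Alternatives were lists of equal length, a −log10 q of at least 3, summit windows of 200 bp, coverage of at least 50% of a region, other assignment limits, 500 bp gene ends, a replicate block, and leaving out libraries. The region counting was tested on simulated lists of 160689 regions with 200 planted per direction for the ChAT-GFP comparison, and 100% of the planted regions came back with 0 wrong calls; regions were drawn independently, so this tests the code and not its power. For the fixed gene lists over 17096 genes, 2.17% of 920 simulated tests without effect had an unadjusted p under 0.05, and 8 planted genes of the NF-kB list gave an adjusted permutation p of 0.0023. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.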

Results

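Open chromatin was profiled by ATAC-seq, in which a transposase cuts and tags accessible DNA, in Th17 cells from mice carrying a ChAT-GFP transgene. ChAT is choline acetyltransferase, the enzyme that makes acetylcholine, and the green fluorescent protein marks cells in which the reporter is active. The series compares ChAT-GFP-positive with ChAT-GFP-negative Th17 cells, with 3 libraries per group. Naive CD4+ T cells from spleen had been activated through CD3 and CD28 with IL-1β, IL-6 and IL-23. The replicate number also names the culture condition: anti-CD28 was plate-bound for replicate 1, soluble for replicate 2, and plate-bound with 0.25 mM sodium butyrate at harvest for replicate 3. The labels do not say whether the libraries came from separate animals, or whether positive and negative cells of 1 number shared a culture. The p-values of tests over libraries therefore measure only the spread between these libraries, which mixes culture condition with what may be technical. Those of the gene-list tests and of Fisher's exact tests rest on genes or regions and measure no spread between libraries.

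Each library was represented by 1 peak list. The lists held 116961, 110554 and 124197 peaks for ChAT-GFP-positive replicates 1, 2 and 3, and 128654, 77644 and 126918 peaks for ChAT-GFP-negative replicates 1, 2 and 3. The lists covered 35.4, 32.0 and 37.6 Mb in the positive group and 38.6, 20.1 and 36.6 Mb in the negative group. The mean was 117237 ± 6826 peaks (SD, n = 3) in positive and 111072 ± 28963 peaks (SD, n = 3) in negative libraries, a difference below the spread between replicates (2-sided exact permutation test, p = 1; the smallest p for 3 against 3 libraries is 0.1). The list of ChAT-GFP-negative replicate 2 was the shortest, and without replicate 2 the difference turned to -7207 peaks. Read depth is unknown from peak lists, so absence from a list was not read as closed chromatin.

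**Figure D1:**
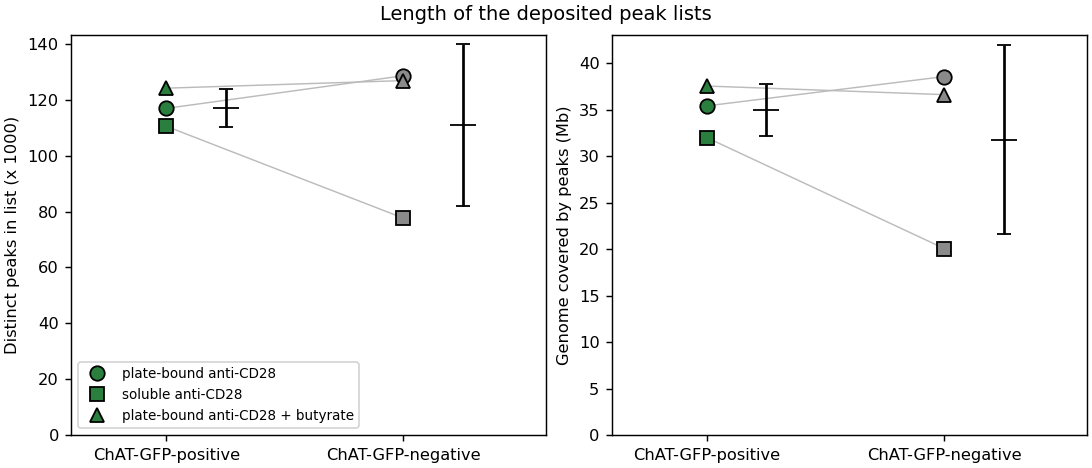
Distinct peaks per list (left, axis in units of 1000) and genome covered (right, Mb) for the 6 libraries. Symbols give the culture, grey lines join the libraries of 1 replicate number, and bars show the mean ± SD of 3 libraries; the soluble anti-CD28 ChAT-GFP-negative list is the shortest, at 77644 peaks and 20.1 Mb.

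The T cell lineage loci examined, and most but not all Th17 core loci, were accessible in every list of both groups. All 16 T cell lineage genes examined, among them Cd3e, Cd4, Lck and Bcl11b, had a peak within 1 kb of a gene end in all 6 lists. So did 12 of 20 Th17 core genes, including the cytokine genes Il17a and Il17f and the receptor gene Il23r. Of the other Th17 core genes, Rora had such a peak in 1 list, Ccr6 in 2, Il22 in 3 and Ccl20 in none. Il17a, which encodes the signature cytokine of these cells, held 12.3 ± 0.577 regions in positive and 10 ± 2.65 regions in negative lists (SD, n = 3, exact permutation p = 0.4), and 7 of its 16 regions were in all 6 lists. Il17f held 8.0 ± 1.0 and 7.67 ± 3.21 regions, and Il23r 17.0 ± 3.61 and 16.7 ± 7.51 regions. Genes of other helper programs had regions within 50 kb in all 6 lists: 8 of 23 regions at Gata3, 6 of 19 at Ifng and 7 of 14 at Csf2 were in all 6 lists. Foxp3, the regulatory T cell factor, held a single region, which was in all 6 lists, and Cd4 held 17 regions, of which 6 were in all 6 lists. A peak within 1 kb of a gene end was in 6 lists at Csf2, 5 at Gata3, 2 at Ifng and none at Foxp3. None of the reference loci named here passed a test of the group difference.

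The comparison the series names is that of ChAT-GFP-positive with ChAT-GFP-negative chromatin. Of 160689 regions in the union of the lists, 538 were in all 3 positive lists and no negative list, and 181 were in all 3 negative lists and no positive list. The positive-only regions included 1 inside Il1r1, the IL-1 receptor gene (chromosome 1, 40224584 to 40224823), and 1 inside Il23r (chromosome 6, 67458812 to 67459025). Others lay nearest Lgals3, which encodes galectin-3 (chromosome 14, 47352374 to 47352567), Il1rn, the IL-1 receptor antagonist gene, and Ctla4, an inhibitory receptor gene. Among naive and memory T cell genes, Bach2 and Foxp1 held 2 positive-only regions each, and Ets1 and Klf2 held 1 each. Other list members with a positive-only region were Egr1, Ptgdr2, Il4ra, Pkm, Pfkp, Hdac4 and Fcgr3. None of the regions named in this paragraph was positive-only in lists of equal length.

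Ranked by the lowest signal percentile among its 3 lists, the leading positive-only region that was also found in lists of equal length lay nearest Neu3, a sialidase gene (chromosome 7, 99797966 to 99798109, percentile 39.5). It was followed by regions nearest Il31, a cytokine gene (chromosome 5, 123471581 to 123471673, percentile 38.3), Coro2b, Pitpnc1, Gm10013, Lpar3, Rfng, Aig1, Ddx19a and the AP-1 gene Fos (chromosome 12, 85455890 to 85456014, percentile 18.0). The lowest of a region's 3 percentiles had a median of 8.89 over the positive-only regions. The negative-only regions included 1 inside Rora, a nuclear receptor gene of Th17 differentiation (chromosome 9, 69072723 to 69073101), 2 nearest the chromatin organiser gene Satb1, and 1 each at Runx3, Bach2, Pfkp and Bank1, none of which was negative-only in lists of equal length. By the same ranking, the negative-only regions also found in lists of equal length were those at Celf5 (chromosome 10, 81465376 to 81465604, percentile 23.1), Ccdc33 and Catsperg2. Tpp2 (percentile 44.7), 1700029H14Rik, En1, Fggy, Zfp800, Clmp and Ptch1 completed the 10 from the deposited lists alone. Bach2 and Pfkp held regions of both directions.

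No gene list was enriched among these regions. Of 46 tests of 23 lists in both directions against random lists matched on regions per gene (1-sided permutation test, Benjamini-Hochberg adjustment), 0 passed an adjusted p of 0.05 and 0 an unadjusted p of 0.05; Fisher's exact test against other regions in exactly 3 lists gave 0 adjusted and 1 unadjusted. The smallest permutation p was 0.0517 (adjusted p = 1), for naive and memory T cell genes, of which 5 of 20 held a positive-only region against 2.1 expected. Th17 core genes held positive-only regions at 2 of 19 genes against 1.47 expected, and pathogenic Th17 genes at 1 of 24 against 1.08 expected. None of the 22 genes of the fixed cholinergic list held a region of either direction; Chrna1, a nicotinic receptor gene outside that list and singled out after its values were seen, was nearest to 1 positive-only region (chromosome 2, 73592638 to 73592793). In lists cut to the 77644 strongest peaks each, 280 regions were positive-only and 202 negative-only. Only 22 of the 538 and 3 of the 181 regions of the deposited lists were among them. Without replicate 2 the order turned, with 1790 and 4004 regions in the deposited lists and 1062 and 1321 in lists of equal length.

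**Figure D2:**
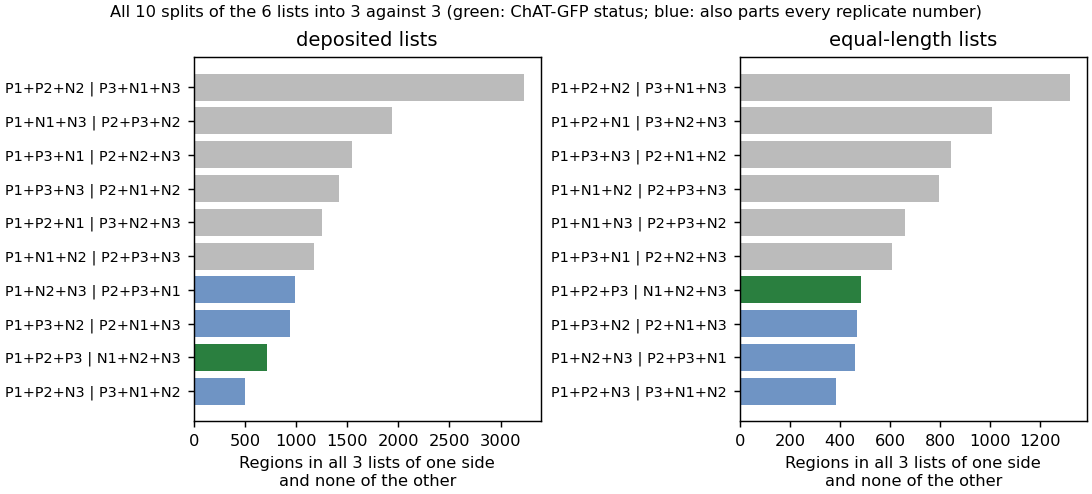
Regions in all 3 lists of one side and in none of the other (horizontal axis) for each of the 10 ways to split the 6 lists, in the deposited lists (left) and lists of equal length (right); P and N are ChAT-GFP-positive and ChAT-GFP-negative lists, numbered by replicate. The split by ChAT-GFP status (green) gave 719 regions in the deposited lists and 482 in lists of equal length, and blue bars are the other splits that part the lists of every replicate number.

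Regions near gene ends made up a larger share of the positive-only than of the negative-only set. Of the positive-only regions 118 of 538 (21.9%) lay within 1 kb of an end of a protein-coding gene, against 25 of 181 (13.8%) of the negative-only regions (2-sided Fisher's exact test, p = 0.0179) and 12.7% of the other regions in exactly 3 lists. The share was 27.8% among regions in all 6 lists. Whole lists showed no such difference, with 21.3% ± 1.08 of regions near a gene end in positive and 21.5% ± 3.28 in negative lists (SD, n = 3, exact permutation p = 1). The negative mean rests on 25.3% in the shortest list, and the other negative lists, at 19.6% and 19.7%, lay below every positive list (20.7% to 22.6%). Across all 6 lists, however, the share fell as the number of regions rose, from 25.3% at 65231 regions to 19.6% at 118100. The order of the lists thus follows their length, and a group difference cannot be told apart from it. The Fisher test counts regions, which are not replicates, and within 500 bp the difference no longer passed (12.5% and 7.18%, p = 0.0557).

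The groups differ in a reporter of Chat, and Chat held more regions in the positive lists. The labels do not say whether the reporter transgene carries Chat sequence, and the lists do not separate reads of such a copy from those of the native locus. Chat held 12, 7 and 15 regions in ChAT-GFP-positive replicates 1, 2 and 3, and 8, 3 and 7 regions in ChAT-GFP-negative replicates 1, 2 and 3. The means were 11.3 ± 4.04 and 6.0 ± 2.65 regions (SD, n = 3), higher in the positive list in 3 of 3 culture conditions, but the difference did not pass (2-sided exact permutation test, p = 0.3, adjusted p = 1). Slc18a3, the vesicular acetylcholine transporter gene that lies within the Chat locus, held 2, 1 and 2 regions in positive and 1, 0 and 0 in negative lists (exact permutation p = 0.2). Of the 20 regions at Chat and Slc18a3, 2 were in all 6 lists (chromosome 14, 32473073 to 32473324 and 32481942 to 32482409). A further 9 were in positive lists only, 4 of them in more than 1 list, and 1 was in a negative list only. None of the 9 was in a list of equal length, and their signal percentiles were low, at 1.77 to 28.2. The 1 in a negative list was in the shortest list, which the cut to equal length leaves whole. No region at either gene was in all 3 positive lists and no negative list. By single peaks in place of merged regions, Chat had a peak within 1 kb of a gene end in all 3 positive lists and no negative list. That count was chosen after seeing the data and was not tested. Of the 20 regions, only the merged Slc18a3 region at 32464679 to 32464952 reaches within 1 kb of an end of Chat. That region was in ChAT-GFP-positive replicates 1, 2 and 3 at signal percentiles of 37.4, 21.3 and 33.7. It was also in ChAT-GFP-negative replicate 1, at a higher percentile of 58.2. The count at the Chat end thus turns on where single peaks of this shared region stop, and is not a separate difference. A region inside Chat (chromosome 14, 32411923 to 32412836) was in every list except the shortest, at signal percentiles of 83.8 to 94.3 in the positive lists and 84.6 and 86.5 in negative replicates 1 and 3. Chat held 6.0 ± 2.65 and 3.33 ± 0.577 regions in lists of equal length (SD, n = 3, exact permutation p = 0.4), where the positive list was higher in 2 of 3 culture conditions and replicate 2 held 3 in each group.

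**Figure D3:**
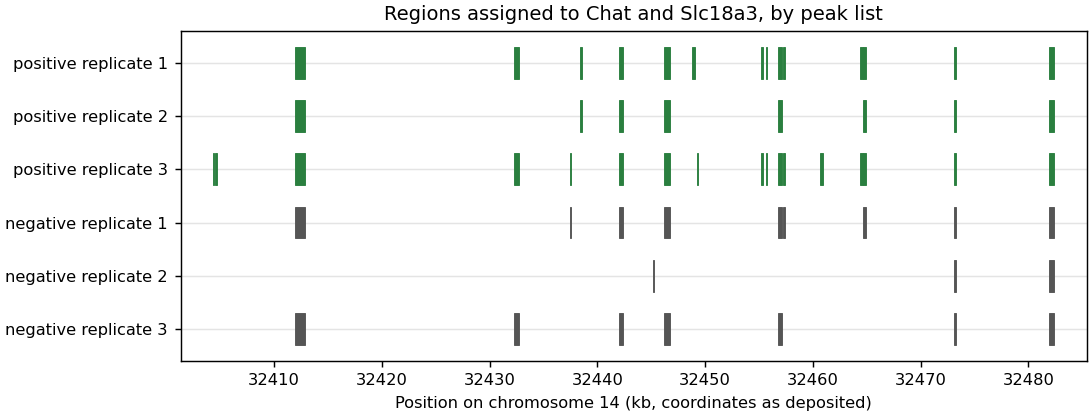
Positions (kb, chromosome 14, coordinates as deposited) of the 20 regions assigned to Chat and Slc18a3 in each of the 6 lists, green for ChAT-GFP-positive and grey for ChAT-GFP-negative; outlines widen the narrowest regions slightly. Positive lists hold 9 regions that no negative list holds, none of which is in a list of equal length. A further 4 regions are missing from the shortest list alone.

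Over the cholinergic genes, the lowest exact permutation p for the group difference was 0.2, at Slc18a3. The smallest possible p of 0.1 let no single gene pass 0.05. Of the 22 genes, 18 held a region, and the mean number of regions was higher in positive lists for 13, lower for 1 and equal for 8, including the 4 with none (Slc5a7, Bche, Chrna7 and Chrna10). The tally was 8 higher, 2 lower and 12 equal in lists of equal length. The choline transporter gene Slc44a1 held 17.3 ± 4.04 and 15.7 ± 7.09 regions, and Ache, which encodes acetylcholinesterase, 10.3 ± 0.577 and 8.33 ± 2.89 regions (SD, n = 3). Receptor genes with regions were Chrna9 (16.7 in positive and 14 in negative lists), Chrm3 (18.3 and 17.3), Chrna5 (4.0 and 3.33), Chrm4 (5.0 and 4.33), Chrm1 (4.0 and 3.67) and Chrm5 (2.67 and 1.67). Chrna4, Chrnb1, Chrnb4 and Ly6h had equal means, Chrnb2, Crat and Lynx1 were higher by 0.333 regions in positive lists, and Chrna2 was lower (2.0 and 2.33). All 22 genes together held 108 ± 11.3 regions in positive and 90.7 ± 33.6 in negative lists (SD, n = 3, exact permutation p = 0.5). The difference of 17.3 regions was 4.5 without replicate 2 and 25.5 without replicate 1, alternatives chosen after seeing the data. Per 1000 regions of a list, the 22 genes held 1.03 ± 0.0510 regions in positive and 0.897 ± 0.0872 in negative lists (SD, n = 3). Every positive list lay above every negative list (exact permutation p = 0.1, the smallest possible, adjusted p = 0.767 over the 23 gene lists). The 22 genes include Chat and Slc18a3, so this value is not separate from the excess of regions there. Nor was it particular to this list, since glycolysis genes were separated as fully (1.31 and 1.22, exact permutation p = 0.1). In lists of equal length the values per 1000 regions were 0.955 ± 0.0812 and 0.887 ± 0.0804 (exact permutation p = 0.5, adjusted p = 1). The totals in lists of equal length were 67.3 ± 6.51 and 62.0 ± 8.66 regions (exact permutation p = 0.6).

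Lists of 1 replicate number, and so of 1 culture condition, resembled each other more than lists of 1 ChAT-GFP status did. The Jaccard index of covered bases averaged 0.643 for lists of the same replicate number and 0.606 for the other pairs, and the pairing by number gave the largest difference of the 15 ways to pair the lists, in the deposited lists and in lists of equal length (exact p = 0.0667, the smallest that 15 ways allow). For ChAT-GFP status the index was 0.606 within and 0.618 between groups. The pairs between groups include the 3 of the same replicate number, which raise that value. Regions found in both lists of 1 culture condition and in no other list numbered 2344 for plate-bound anti-CD28, 213 for soluble anti-CD28 and 3132 for plate-bound anti-CD28 with butyrate, ranking 3, 12 and 1 among the 15 pairs of deposited lists. In lists of equal length these counts were 867, 667 and 1305, the 3 highest of the 15 pairs. The strongest such region of the plate-bound culture lay inside Snd1 (chromosome 6, 28929141 to 28929699), and those of the butyrate culture inside Dcun1d5 (chromosome 9, 7199858 to 7200057) and Gask1a (chromosome 9, 121956686 to 121956843). With 1 replicate number per culture condition, condition and number cannot be told apart, and the counts of regions per condition were not tested. The butyrate culture also had plate-bound anti-CD28, so regions of the plate-bound culture alone cannot be credited to plate-bound anti-CD28.

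**Figure D4:**
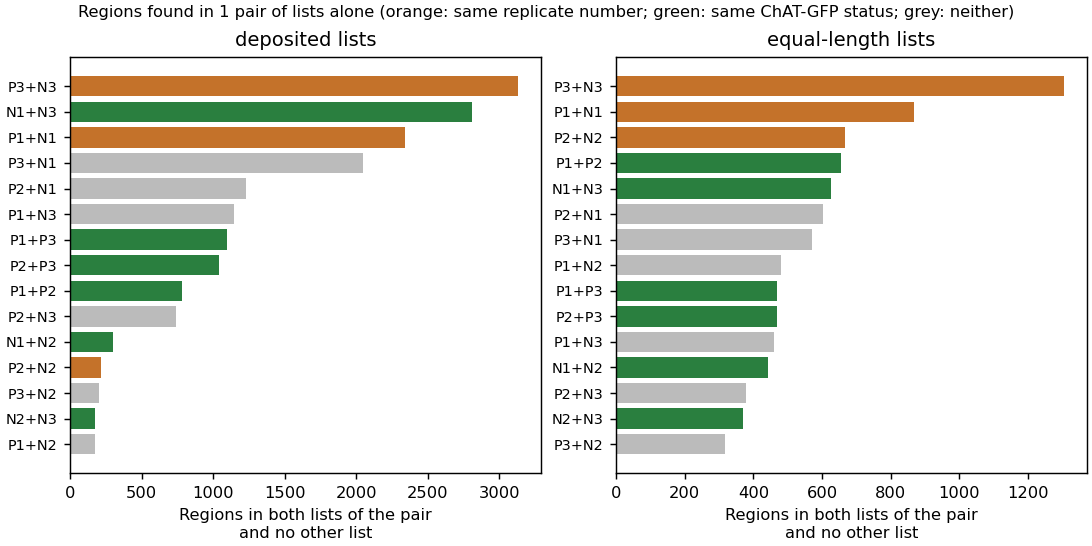
Regions found in both lists of a pair and in no other list (horizontal axis) for the 15 pairs, in the deposited lists (left) and lists of equal length (right); orange pairs share a replicate number, green pairs share ChAT-GFP status, and P and N are ChAT-GFP-positive and ChAT-GFP-negative lists, numbered by replicate. In lists of equal length the 3 pairs of 1 replicate number share the most, at 1305, 867 and 667 regions.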

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

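Lists of equal length, leaving out replicates and the count over splits were planned before the data were examined, but leaving out replicates within lists of equal length was chosen after seeing the data. The expected outcomes of the tests in this part, the bound of 1.5 included, were written down only after the counts were seen.

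The number of peaks, ChAT-GFP-positive minus ChAT-GFP-negative, was 32910 in the soluble anti-CD28 culture and -11693 and -2721 in the other cultures. It stood out because the cultures differ in direction, with 1 pair per culture, and the difference was not tested.

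Positive-only regions outnumbered negative-only regions by 2.97 to 1 in the deposited lists, by 8.74 to 1 with −log10 q of at least 3, and by 4.48 to 1 where peaks had to cover 50% of a region. The short list of ChAT-GFP-negative replicate 2 is a candidate explanation for part of the excess, since a region missing from that list counts more easily as positive-only: in lists of equal length the ratio was 1.39, under the bound of 1.5 set for it. Without replicate 2 the ratio was 0.447 in the deposited lists. There both negative lists were longer than both positive lists, so list length alone could turn the ratio, and no conclusion is drawn from it. In lists of equal length the ratio without replicate 2 was 0.804, so replicates 1 and 3 by themselves did not show the excess. This setting was chosen after seeing the data, and the ratio moved with the replicate left out. It therefore does not decide whether chromatin opened in ChAT-GFP-positive cells is a source of the excess. Leaving out a replicate also asks for fewer lists per group. With the short list kept, the ratio without replicates 1 and 3 was 6.67 and 2.85 in the deposited lists, and 1.95 and 1.45 in lists of equal length, where 1.95 lies above the bound. Why that list is short, and a smaller difference between the groups, stay open.

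The split by ChAT-GFP status gave 719 regions in the deposited lists, and 9 of the 10 splits, the real one included, gave as many; the highest other gave 3230. In lists of equal length it gave 482 regions, 7 of the 10 splits gave as many, and the highest other gave 1319. In both settings the highest split set the 3 longest deposited lists against the 3 shortest, a structure of the libraries other than ChAT-GFP status. The 3 other splits that part the lists of every culture, a comparison planned before the data were examined, gave 500 to 989 regions in the deposited lists and 383 to 466 in lists of equal length. In the latter, the 482 regions of the real split were the most of these 4. Neither 10 nor 4 splits are enough for a share under 0.05.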

How the results depend on the processing

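Leaving out replicates for the cholinergic genes was chosen after seeing the data. Motif alternatives were not run. Lists of equal length gave 280 positive-only regions, and 867, 667 and 1305 regions of the plate-bound, soluble and butyrate cultures; the cause was not tested. With −log10 q of at least 3 there were 61 negative-only regions and 86 of the soluble culture, in which the short list lost the largest share of peaks. Leaving out replicates or single libraries, which asks for fewer lists, gave 619 to 4126 positive-only and 320 to 4004 negative-only regions. Without replicate 2 the group difference reversed to -7207 peaks and -1.11 Mb (ranges -7207 to 15095 peaks and -1.11 to 6.43 Mb). Within 500 bp the gene-end difference was 5.27 points and no longer passed. In lists of equal length the difference in regions reversed to -0.667 at Slc44a1, 0.333 at Chrna2 and -0.333 at Ifng; the cause was not tested.

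The replicate numbers mark no shared litter, batch or day in the labels, but each names a culture condition shared by a positive and a negative library. Same-numbered lists had correlations of deviations of 0.0687, 0.106 and 0.119 in the deposited lists, and 0.0763, 0.114 and 0.184 in lists of equal length. Since not all were above 0.1, the main tests did not pair the libraries, although the design blocks them by condition. Each list correlated best with its own number, the others lying between -0.0803 and -0.0243 in the deposited lists. With the number as a block, 6148 regions were higher in positive and 4117 in negative lists in at least 2 pairs and the other way in none. Sign flips left the list differences at 6165 peaks (exact p = 1) and 3.24 Mb (exact p = 0.75).

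No gene list passed under any alternative run, similarity kept its direction, and Chat kept more regions in positive lists, by 2.67 to 6.0. Unknown depth limits every statement on absence.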

Other observations

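Counts of gene ends with a peak, regions per 1000 of a list, gene lists per culture and the rank of Chat were chosen after seeing the data. Tests written down after their result are those of list length at Chat, of shared regions within a replicate number and of the number of gene lists past the threshold.

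Markers of other cell types were counted by gene ends, and differences between the groups were not tested. Peaks within 1 kb of a gene end were found at 4.67 ± 0.577 of 12 B cell genes in positive and 3.67 ± 0.577 in negative lists (SD, n = 3), with Ebf1 and Cr2 in all 6 lists and Cd79b, Ms4a1 and Pax5 in none. Myeloid and dendritic cell genes had 8.0 and 8.33 of 17, with Spi1 and Cebpa in all 6 lists and Lyz2, Itgam and Adgre1 in none. CD8 T and NK cell genes had 5.0 and 4.67 of 13, and erythroid genes 4.33 and 4.33 of 10, with none at the globin genes Hba-a1 and Hbb-bs. Among activation-linked groups, 15 of 16 AP-1 and BATF genes had such a peak in all 6 lists, as did 13 of 15 NF-kB genes, 19 of 22 cell cycle genes, 13 of 16 glycolysis genes and 14 of 15 follicular helper genes. The other lists had 8 of 22 cholinergic, 14 of 24 pathogenic Th17, 10 of 15 non-pathogenic Th17, 10 of 15 Th1, 8 of 14 Th2, 11 of 14 regulatory, 17 of 20 naive and memory, 16 of 20 activation, 10 of 12 inhibitory receptor, 13 of 20 chemokine receptor and homing, 9 of 12 histone deacetylase and 9 of 17 adrenergic and neuropeptide receptor genes in all 6 lists.

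Glycolysis genes were the list nearest the threshold among regions of 1 culture. In lists of equal length 5 of 16, Gapdh, Pgam1, Eno1, Pkm and Ldha, held a region of the plate-bound culture without butyrate against 0.902 expected (permutation p = 0.0017, adjusted p = 0.0966). T cell activation genes held regions of the butyrate culture at 10 of 20 against 4.35 expected, among them Cd69, Il2ra, Icos and Irf4 (permutation p = 0.0028, adjusted p = 0.0966). None of the 69 tests passed after adjustment in either setting; 2 in the deposited lists and 5 in lists of equal length had an unadjusted permutation p under 0.05. In the deposited lists the glycolysis value was 7 of 16 against 2.31 expected (adjusted permutation p = 0.214), and activation genes held 5 of 20 against 7.41 expected.

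Chat had the largest excess of regions in positive lists among the 914 genes with a like number of regions (16 to 20), at 5.33 regions against a median of 0.667. The short list is argued against as the whole source: without replicate 2, 0.109% of those genes, Chat alone, differed as much. Unequal list lengths are argued against only as the whole source: in lists of equal length the excess fell to 2.67 regions, and 0.235% of 2555 genes (6 genes) differed as much. These shares rank Chat among genes of the same lists and measure no spread between libraries. Without replicate 3 the share was 3.39% (31 of 914 genes), so replicate 3 carries part of the rank. Extra copies of the Chat segment may add peaks, and this stays open: regions of neighbouring genes differed by 1.33 per list in lists of equal length (11.3 ± 1.53 and 10 ± 1.0; SD, n = 3), within its error of the bound of 1, and by 4 per list in the deposited lists (18.7 and 14.7, exact permutation p = 0.4). A copy carried by the reporter transgene would be in both groups if, as labelled, their genotype is the same. Its number alone would then not favour the positive lists. Greater accessibility of Chat in cells with an active reporter is a hypothesis that these lists leave open.

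Taken over the 3 pairs, lists of 1 replicate number shared the most regions found nowhere else of the 15 ways to pair the lists. Of the 15 single pairs, these 3 took the top 3 ranks in lists of equal length but not in the deposited lists, where the butyrate pair ranked 1 with 3132 regions, the plate-bound pair 3 with 2344 and the soluble pair 12 with 213. Unequal lengths of the lists are argued against as the source, since in lists of equal length only 1 of the 15 ways to pair the lists, that by number, shared as many (2839 regions, the next 2401). The shared culture condition of the number could be the source, and so could a shared preparation: each culture condition has 1 replicate number, so the explanations cannot be told apart.

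The difference of 8.12 points in the share of regions near a gene end was matched by 4 of the 10 splits, the real one included, with 19.4 points the highest other. The number of gene lists past the threshold was 0 in the real split and in each of the others (10 of 10 splits, highest other 0). The 10 splits are too few for a share under 0.05. Among the 20 groups of 3 lists, 3 had a gene-end share as high as that of the positive-only regions, the positive group itself included, and the highest other was 29.4%.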
